A study of Mus musculus with 6 samples.

How the data were processed

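RNA of hair follicle stem cells sorted from mouse skin was measured on 6 Affymetrix GeneChip Mouse Gene 2.0 ST arrays, 1 array per sample, with 3 wild-type (WT) and 3 K14-sPLA2-IIA transgenic (TG) samples. Genotype and replicate number were taken from the sample labels. Per the labels' protocols, the cells were sorted by flow cytometry on CD34 and α6-integrin, and the material hybridised came from total RNA and carried a biotin label. The submitters' processing notes name Affymetrix Expression Console 1.4.1 and Transcriptome Analysis Console, with no role or settings. The labels do not say whether the 3 samples of a genotype came from different mice, so the p-values measure only the spread between these samples.

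The values used here are the authors' deposited expression values on a log2 scale, 1 per array and transcript cluster (called a feature below). The scale was read from the values, which run from about 3 to 14 with nearly equal quartiles on the 6 arrays. The log base, the summarisation method and any scaling between arrays are not given in the sources used here. If the base is not 2, the fold changes below do not hold, while the directions and p-values do. No background or detection value was used, so no gene is called absent, and low values can understate a difference. For arrays, the number of samples limits the precision, since there is no read depth.

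The table held 41345 features. The platform annotation gave exactly 1 gene symbol for 23521 of them, several for 1814 and none for 16010. The Entrez gene ID of 23328 one-symbol features was found in a RefSeq gene table of assembly GRCm38.p6, which was used for names only, and 0 symbols needed updating. The sources used here name no genome build, and no coordinates are given. Features with several symbols or none were left out of the main test. Where a gene had several features, the one with the highest mean over all arrays was used, which left 22180 genes. For 188 of the 1082 genes with several features, the brightest feature and the mean of the features differed in the sign of the TG minus WT difference. No gene was removed for a low value, and the values were not scaled again.

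TG was compared with WT gene by gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Differences are TG minus WT on the log2 scale, with the standard error (SE) of the moderated fit. A set of 43 gene lists was tested with camera from limma on the same values, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 43 lists. The lists covered follicle and epidermal compartments, signalling and metabolic pathways, stress responses and cell types that a skin sort can carry along. Of 1215 list entries, 1116 matched a tested gene by symbol, and some genes stand in more than 1 list. Within each list, p-values were also adjusted over the list alone, with no correction across the 43 lists. Some such calls can therefore arise without a difference. Camera with a correlation estimated from the arrays, camera on ranks and the self-contained test fry were run as alternatives. List differences are means over members of the TG minus WT difference.

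Lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule named, in each direction, up to 12 genes with the largest difference among those past the threshold whose arrays did not overlap between genotypes. Places left over went to the genes with the smallest unadjusted p among those at least 1.5-fold apart without overlap, which are given as values with no claim of change. Pla2g2a, a few stem cell and JNK pathway genes (Cd34, Itga6, Krt15, Sox9, Lhx2, Lgr5, Jun, Fos, Mapk8 and Mapk9) and up to 4 members with the smallest p of each list could be named whatever their p. Predicted genes, clone names, small RNAs and receptor multigene families were counted but not named by this rule.

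Both genotypes carry the replicate numbers 1 to 3. Deviations from the genotype means correlated over all genes at 0.20 between the arrays numbered 1, 0.67 between those numbered 2 and 0.74 between those numbered 3. Since each exceeded the limit of 0.1 set for this check, arrays with the same number were treated as pairs in an alternative fit with the replicate number as a block. The pairing comes from this data check alone, as the labels state no shared day or litter. It is weakest for number 1, where WT array 1 correlated more closely with TG array 2 (0.50) than with TG array 1. WT array 2 and TG array 1 (0.17) exceeded the limit too, so the check did not single out pairing by number. Deviations cancel within a genotype, so the match of the arrays numbered 3 alone favours positive values among the others. All paired counts below rest on this choice.

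The gene test was tested on simulated data in which 200 of 22180 genes were changed in TG, with genes varying independently. It recovered 44% of the genes changed by 1 on the log2 scale, 88% of those changed by 2, 94% of those changed by 4 and 100% of those changed by 6. Of 173 genes called, 10 were unchanged ones. The Benjamini-Hochberg adjustment demands less of each gene when many genes differ, so these shares can overstate recovery where few do. A gene not called in the real data is therefore not shown to be unchanged. A further 100 simulations of the TG against WT comparison on 22180 genes held no group difference and kept the correlation between genes, with arrays varying independently. In these, camera with the preset correlation called a median of 10 of the 43 lists (quartiles 7 and 13), and at least 8 lists in 72 simulations. Camera with an estimated correlation called any list in 1 simulation, fry in 2, and the gene test any gene in 3. A call by the preset correlation alone is therefore weak evidence here. Recovery of shifted lists was not simulated with an estimated correlation or by fry. A list that they do not call is therefore not shown to be unchanged.

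The alternatives were quantile normalization, centring arrays on their medians, 2 filters on dim genes, the mean of a gene's features, all features, 3 variance models, array weights, the replicate block, other thresholds, and leaving out each array in turn. Added after seeing the data were leaving out both arrays of a number and, as a covariate, the per-array mean of the suprabasal list or of the T-cell list. The estimated correlation under each of these settings other than the robust and unmoderated variances was added after seeing the data too. The array weights were 4.23, 0.96 and 0.33 for TG arrays 1 to 3, and 1.31, 1.95 and 0.29 for WT arrays 1 to 3. Results with array weights thus rest largely on TG array 1 within TG.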

Results

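Expression was measured in hair follicle stem cells, the slow-cycling cells of the follicle bulge, sorted from mouse skin at postnatal day 49. In normal mice this age falls in the telogen, or resting phase, of the hair cycle. There were 3 WT arrays and 3 TG arrays. TG mice carried a K14-sPLA2-IIA transgene. Secreted phospholipase A2 group IIA, encoded by Pla2g2a, releases fatty acids from membrane phospholipids, and keratin 14 promoters drive expression in basal keratinocytes and the outer root sheath. The comparison asked how expression in the sorted stem cells differed with the transgene. The median of all features lay between 5.90 and 5.99 on the log2 scale on the 6 arrays, and the median TG minus WT difference over all genes was -0.0075.

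Pla2g2a was far higher in TG cells. Its log2 value was 12.52 ± 0.12 in TG (SD, n = 3) and 6.14 ± 0.55 in WT (SD, n = 3). The 3 TG arrays read 12.61, 12.57 and 12.39, and the 3 WT arrays 6.77, 5.75 and 5.90. The difference of 6.38 ± 0.27 (SE) corresponds to 83.4-fold, with an adjusted p of 0.00255 in limma. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays can give. The labels do not state the species of the transgene or whether the array's probes lie in it. Pla2g2a lost its call without TG array 1 (adjusted p = 0.065 in limma), where its difference was 6.34.

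Pla2g2a was the only gene of 22180 past the threshold in limma, and 0 genes were lower. At an unadjusted p under 0.05 there were 428 genes higher and 187 lower in TG, 615 in all. Chance gives 1109 for independent arrays, but arrays with the same number were correlated, and the 3 other splits of the arrays that part all pairs gave 259, 180 and 164. With arrays paired by number the total was 1874, against 829, 669 and 636 for those splits, and Pla2g2a was again the 1 gene past the adjusted threshold (adjusted p = 0.00428). The 2 genotypes did not overlap for 884 genes higher and 712 lower in TG, or 7.20% of genes, where chance gives 10% for independent arrays and those 3 splits gave 4.82%, 3.99% and 4.01%. Of these, 130 were at least 1.5-fold higher and 46 at least 1.5-fold lower.

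The genes next in rank on the higher side were not past the threshold and are given as values. Jun and Fosb, which encode subunits of the AP-1 transcription factor, differed by 1.21 ± 0.24 and 1.38 ± 0.29 (SE). Csrnp1, which encodes a nuclear protein, differed by 1.85 ± 0.29, or 3.59-fold. Ifrd1, a transcriptional co-regulator gene, differed by 1.05 ± 0.21. Dlgap5 and Haus1, whose products act at the mitotic spindle, differed by 0.75 ± 0.14 and 0.75 ± 0.16. Hk2, encoding the glycolytic enzyme hexokinase 2, differed by 0.78 ± 0.15, and Atp5mpl, whose product associates with ATP synthase, by 0.81 ± 0.18. Gpc4, a glypican gene, differed by 1.01 ± 0.21. Ddias and Sema6a, a semaphorin gene, differed by 0.87 ± 0.18 and 0.69 ± 0.15. In all of these the 3 TG arrays lay above the 3 WT arrays, and the adjusted p was 0.99996.

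On the lower side the matrix gene Fn1, encoding fibronectin, differed by -0.77 ± 0.18 (SE), and Igfbp3, encoding a binding protein of insulin-like growth factors, by -1.04 ± 0.22. Clec2d, a C-type lectin gene, differed by -0.96 ± 0.22 and the sulfotransferase gene Sult5a1 by -0.90 ± 0.17. Slc27a3, of the fatty acid transport protein family, differed by -0.74 ± 0.17. Srgap1 differed by -0.76 ± 0.18, the reticulon gene Rtn2 by -0.74 ± 0.18 and Naip2 by -0.60 ± 0.15, the last at a low level (4.51 in WT and 3.90 in TG). The zinc finger genes Zfp568 and Zfp992 differed by -0.75 ± 0.16 and -0.65 ± 0.12, Nrip3 by -0.60 ± 0.14 and Cstad by -0.59 ± 0.15. In each the 3 TG arrays lay below the 3 WT arrays, with an adjusted p of 0.99996.

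**Figure D1:**
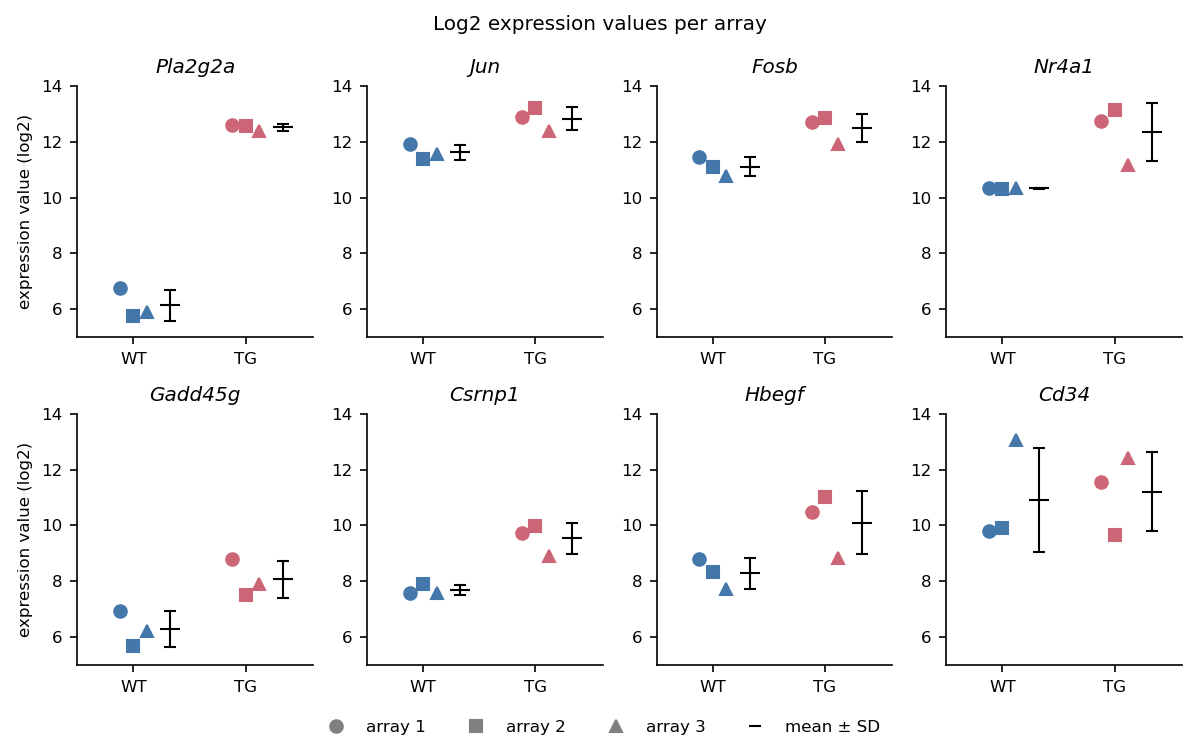
Log2 expression value (vertical axis) of 8 genes on the 3 WT arrays (blue) and the 3 TG arrays (red), with the mean ± SD beside them; the symbol shows the array number. The TG arrays lie above the WT arrays for Pla2g2a (mean 12.52 against 6.14), Jun, Fosb, Nr4a1, Gadd45g, Csrnp1 and Hbegf, while the genotypes overlap for Cd34 (11.21 ± 1.42 against 10.92 ± 1.87). Csrnp1, Fosb, Nr4a1, Gadd45g and Hbegf were named for lack of overlap or a small p, so their separation is not a test. Fos and Junb, whose genotypes overlap, are not shown.

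Of the 43 gene lists, 7 were higher and 1 was lower in TG by camera with the preset correlation. With an estimated correlation 0 lists passed (lowest adjusted p = 0.646) and by fry 0 passed (lowest adjusted p = 0.865), with 0 lists at an unadjusted p under 0.05 in either. Camera with the preset correlation also called 8 or more lists in 72 of 100 simulations without a group difference, so 8 calls were not unusual there. The simulated arrays varied independently, unlike the real arrays with the same number. The 3 other splits of the real arrays that part all pairs gave 12, 9 and 6 lists by this test. Adjusted over the list alone, 9 list memberships were higher and 0 lower, against 1 gene (Pla2g2a) adjusted over all genes. Paired by number, 32 were higher and 4 lower, and 9 lists were higher and 3 lower by camera with the preset correlation. Paired, 0 lists passed with an estimated correlation (lowest adjusted p = 0.710, 1 list at an unadjusted p under 0.05) and 0 by fry (lowest adjusted p = 0.289, 6 lists at an unadjusted p under 0.05).

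Immediate early genes, which cells switch on within minutes of a stimulus and also during tissue dissociation, had the largest mean difference of the 43 lists. It was 0.73, with 27 of 28 members above 0 (adjusted p = 1.9e-16 by camera, and adjusted p = 0.646 with an estimated correlation). Adjusted over the list alone but not over all genes, 5 members passed as higher in TG and 0 as lower. These were Nr4a1 with 2.02 ± 0.48 (SE), Nr4a3 with 1.21 ± 0.30, both orphan nuclear receptor genes, Gadd45g with 1.80 ± 0.43, Fosb with 1.38 ± 0.29 and Klf2 with 0.64 ± 0.14. Nr4a3 is outside the naming rule and was chosen after its values were seen. Btg2, an antiproliferative gene, differed by 1.31 ± 0.45. Paired by number, 19 members were higher adjusted over the list alone. The list mean was lower on the arrays numbered 3 than on the other arrays of their genotype, by -0.48 in WT and -0.94 in TG.

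The JNK and AP-1 list covers the c-Jun N-terminal kinase pathway and its target transcription factors, and shares 4 genes with the immediate early list. Adjusted over the list alone but not over all genes, 2 members passed as higher in TG and 0 as lower. These were Jun with 1.21 ± 0.24 (SE) and Fosb with 1.38 ± 0.29, and 5 members were higher when paired by number. Atf3 differed by 1.26 ± 0.37, Junb by 0.81 ± 0.37 and Fos by 0.53 ± 0.48. The JNK kinase genes Mapk8 and Mapk9 differed by 0.09 ± 0.18 and 0.40 ± 0.32, and Mapk8 turned to -0.054 without TG array 1. Of the 26 members 13 lay above 0, the mean difference was 0.22 and the median 0.028, and the list did not pass (adjusted p = 0.158 by camera). It passed without TG array 3, with a mean difference of 0.37 (adjusted p = 0.00129), and without both arrays numbered 3, with 0.30 (adjusted p = 0.00209). Neither call held with an estimated correlation (adjusted p = 0.514 and adjusted p = 0.628). The mean was 0.11 without TG array 2 and 0.14 without WT array 3, with neither past the threshold.

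All 43 measured cell cycle genes had a difference above 0, with a mean of 0.61 (adjusted p = 3.7e-29 by camera, and adjusted p = 0.646 with an estimated correlation). None passed adjusted over the list alone, where 17 had an unadjusted p under 0.05, and 1 was higher when paired by number. Birc5, encoding survivin, differed by 1.11 ± 0.35 (SE), and Hmmr, whose product acts at the spindle, by 0.88 ± 0.26. Ube2c, encoding a ubiquitin-conjugating enzyme of the anaphase-promoting complex, differed by 0.83 ± 0.27 and the spindle checkpoint gene Bub1b by 0.80 ± 0.24. The 2 genotypes were farthest apart on the arrays numbered 3, and without both of them the mean difference was 0.28. The list of quiescence genes and cell cycle inhibitors did not pass (mean 0.20, adjusted p = 0.0824 by camera) but did without TG array 3 (adjusted p = 0.0268, and adjusted p = 0.514 with an estimated correlation), with Id1 at 0.61 ± 0.25.

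Genes of oxidative phosphorylation had a mean difference of 0.25, with 42 of 43 members above 0 (adjusted p = 4.6e-16 by camera, and adjusted p = 0.646 with an estimated correlation). None passed adjusted over the list alone, and 6 had an unadjusted p under 0.05. The respiratory chain genes Ndufb6, Uqcrq and Ndufa1 differed by 0.51 ± 0.16, 0.50 ± 0.19 and 0.46 ± 0.17 (SE), and Cycs, encoding cytochrome c, by 0.47 ± 0.17. The mean was 0.16 without WT array 3. Cytosolic ribosomal protein genes had a mean difference of 0.14, with 37 of 41 above 0 (adjusted p = 8.4e-05 by camera, and adjusted p = 0.846 with an estimated correlation). Rps27 differed by 0.51 ± 0.16, Rpl37 by 0.43 ± 0.17, Rps25 by 0.42 ± 0.16 and Rps20 by 0.29 ± 0.15, and none passed adjusted over the list alone. In WT, Rps27, Rpl37 and Rps20 read 6.81, 4.79 and 6.83, well below the list mean of 10.02. The ribosomal call was lost without WT array 3 (mean 0.041, adjusted p = 0.278) and without TG array 1 (mean 0.076, adjusted p = 0.0557), and the mean was 0.23 without TG array 3.

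Stress and wound keratins and alarmins, which keratinocytes make after injury, had a mean difference of 0.38, with 18 of 20 above 0 (adjusted p = 4.0e-06 by camera, and adjusted p = 0.646 with an estimated correlation). The largest named difference was that of Hbegf, encoding a ligand of the EGF receptor, at 1.82 ± 0.57 (SE). The wound keratin gene Krt6a differed by 0.92 ± 0.45 and the defensin gene Defb4 by 0.22 ± 0.12. None passed adjusted over the list alone, and 2 members were higher when paired by number. The mean was 0.23 without WT array 3, 0.24 without TG array 2 and 0.58 without TG array 3. The outer root sheath list, which shares the keratins, had a mean of 0.40 with 9 of 10 above 0 (adjusted p = 0.0104 by camera, and adjusted p = 0.646 with an estimated correlation). In it Dcn differed by 0.92 ± 0.44, Barx2 by 0.76 ± 0.38 and Krt17 by 0.23 ± 0.14. None passed adjusted over the list alone, and 1 member was higher when paired by number. Its call was lost without WT array 2 (mean 0.28, adjusted p = 0.195) and without TG array 1 (mean 0.26, adjusted p = 0.139). On all 6 arrays it was lost with genes above the median level (adjusted p = 0.0687) and with no moderation (adjusted p = 0.0673), while array weights moved the mean to 0.66.

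Markers of the stem cells themselves varied more between arrays of 1 genotype than between genotypes. Cd34 read 9.78, 9.89 and 13.07 on WT arrays 1 to 3 and 11.57, 9.65 and 12.42 on TG arrays 1 to 3, a difference of 0.29 ± 1.05 (SE). Lgr5, a bulge and hair germ marker, differed by 0.35 ± 1.14, and the transcription factor genes Sox9 and Lhx2 by 0.45 ± 0.45 and 0.29 ± 0.36. Krt15 and Itga6, encoding α6-integrin, differed by 0.06 ± 0.13 and -0.07 ± 0.18. Of these genes, Cd34, Lgr5, Krt15, Lhx2 and Itga6 changed sign when 1 array was left out. Without TG array 3, Cd34 was at -0.31, Lgr5 at -0.35 and Itga6 at 0.062, and without TG array 1 Krt15 was at -0.0034 and Lhx2 at -0.0097. Without WT array 1, Cd34 was at -0.27 and Lgr5 at -0.28, and without WT array 2 at -0.22 and -0.16.

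The bulge marker list had a mean difference of 0.28, with 33 of 37 members above 0 (adjusted p = 0.00757 by camera, and adjusted p = 0.846 with an estimated correlation). No member had an unadjusted p under 0.05. Id2 differed by 0.83 ± 0.55 (SE), Runx1 by 0.42 ± 0.26, Foxc1 by 0.39 ± 0.20 and Id4 by 0.36 ± 0.21. The suprabasal and terminal differentiation list, of genes of the outer epidermis, was lower, with a mean of -0.32 and 30 of 38 below 0 (adjusted p = 0.0455 by camera, and adjusted p = 0.852 with an estimated correlation). The cornified layer genes Flg2, Cdsn and Lor differed by -1.32 ± 0.89, -1.05 ± 0.69 and -0.82 ± 0.63, and the lipoxygenase gene Aloxe3 by -0.87 ± 0.48. Both calls changed with single arrays and with the processing. Without TG array 3 the bulge mean was 0.011 (adjusted p = 0.840) and the suprabasal mean 0.18 (adjusted p = 0.368). Without WT array 1 they were 0.017 and -0.069, without WT array 2 0.028 and -0.049, and without TG array 1 0.17 (adjusted p = 0.139) and -0.35 (adjusted p = 0.0557), with neither past the threshold. Without WT array 3 they were 0.78 and -0.85, and without TG array 2 0.64 and -0.80, with both past it. On all 6 arrays the bulge call was lost with quantile normalization (adjusted p = 0.0504), genes above the median level (adjusted p = 0.0883) and no moderation (adjusted p = 0.0517), and the suprabasal call with all features (adjusted p = 0.102) and no moderation (adjusted p = 0.175). Array weights moved the means to 0.72 and -0.58.

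The 2 arrays numbered 3 stood apart from the rest. The first principal component held 64.6% of the variance, and WT array 3 (score 50.2) and TG array 3 (53.3) lay opposite WT array 1 (-32.7), WT array 2 (-33.6) and TG array 2 (-34.3), with TG array 1 between them (-2.78). On array 3 the bulge list mean was higher than on the other arrays of its genotype by 1.52 in WT and 0.80 in TG. The suprabasal list mean was lower there, by -1.59 and -1.51, and so was that of the haematopoietic and T-cell list, by -1.19 and -1.29.

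**Figure D2:**
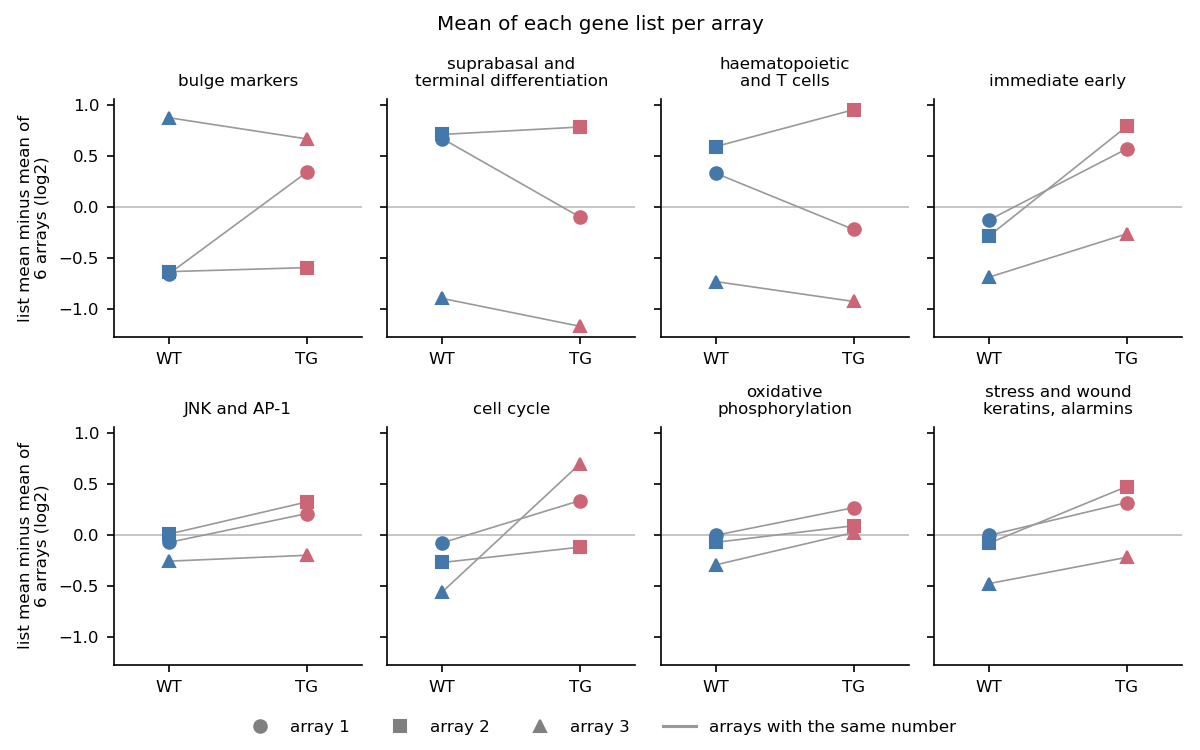
Mean of the members of 8 gene lists on each array, minus the mean of the 6 arrays (log2, vertical axis), for WT (blue) and TG (red); lines join arrays with the same number. The arrays numbered 3 are highest for bulge markers and lowest for the suprabasal and T-cell lists in both genotypes. Each TG array lies above the WT array of its number for immediate early, JNK and AP-1, cell cycle, oxidative phosphorylation and stress keratin genes.

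Of 11 lists of markers of other cells that a skin sort can hold, 0 passed by camera in the unpaired fit of the 22180 genes without weights or covariates (lowest adjusted p = 0.125). With array weights the T-cell (adjusted p = 0.00344), melanocyte (adjusted p = 0.0178) and Schwann lists (adjusted p = 0.0195) passed as lower, and none of them did with an estimated correlation (adjusted p = 0.723, 0.691 and 0.550). The haematopoietic and T-cell list had a mean difference of -0.13 with 4 of 20 members above 0 (adjusted p = 0.289 by camera), and this turned to 0.30 without TG array 3, to 0.14 without WT array 2 and to 0.0050 without WT array 1, and was -0.051 without TG array 1. It passed as lower without WT array 3 (-0.53, adjusted p = 0.00364) and without TG array 2 (-0.64, adjusted p = 2.0e-07). Without WT array 3 the melanocyte list passed as lower (adjusted p = 0.00218) and the endothelium list as higher (adjusted p = 0.00364), the latter also without TG array 1 (adjusted p = 0.0480). With an estimated correlation these calls without an array were lost too (adjusted p = 0.773 or higher). Without both arrays numbered 2, the T-cell (adjusted p = 0.000499 by camera) and macrophage lists (adjusted p = 0.0357) passed as lower. Without both numbered 3, the melanocyte (adjusted p = 0.000859) and Schwann lists (adjusted p = 0.0405) did. These calls were lost with an estimated correlation (adjusted p = 0.929 and 0.628). In the other cell lists, the macrophage gene Adgre1 differed by -0.52 ± 0.21 (SE) and the Merkel and simple epithelial keratin gene Krt18 by 0.30 ± 0.12. The macrophage list had a mean of -0.080 with 8 of 21 members above 0 (adjusted p = 0.330 by camera). The Merkel list had a mean of -0.063 with 6 of 12 above 0 (adjusted p = 0.998 by camera), so Krt18 went against its list mean. The Schwann cell and nerve list passed when paired by number (mean -0.14, adjusted p = 0.125 by camera, and adjusted p = 0.0411 paired). So did the desmosome and tight junction list (mean -0.13, adjusted p = 0.158, and adjusted p = 0.0227 paired), which was at 0.026 without TG array 3, -0.046 without WT array 1 and -0.034 without WT array 2, and passed without WT array 3 (-0.32, adjusted p = 0.00589) or TG array 2 (-0.28, adjusted p = 0.010). So did the infundibulum and isthmus list (mean 0.19, adjusted p = 0.110, and adjusted p = 0.00495 paired), with Plet1 at 0.27 ± 0.20 and Lrig1 at 0.22 ± 0.14, and the BMP and TGF-β list (mean 0.17, adjusted p = 0.110, and adjusted p = 0.0239 paired). For each of these 4 lists the paired call was lost with an estimated correlation (adjusted p = 0.710). Each also passed with array weights, which rest largely on TG array 1 within TG. The infundibulum list passed without TG array 3 (0.41, adjusted p = 0.00201), and the BMP list without WT array 3 (0.33, adjusted p = 0.00144) or TG array 2 (0.28, adjusted p = 0.0282). The infundibulum mean was lower without TG array 2 (0.065), WT array 3 (0.095) or TG array 1 (0.098), and the BMP mean without WT array 1 (0.079), WT array 2 (0.11) or TG array 3 (0.11), with none past the threshold. With an estimated correlation 0 lists passed with array weights (lowest adjusted p = 0.550, 0 lists at an unadjusted p under 0.05) or without any 1 array (lowest adjusted p = 0.514, 0 to 3 lists).

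Among the genes of lipid mediators, Pla2g2a was the only one of 24 measured phospholipase A2 family members past the threshold, adjusted over the list alone as well. The others with the smallest p were Pla2g7 at 0.96 ± 0.54 (SE), Plaat3 at -0.46 ± 0.28 and Pnpla6 at -0.32 ± 0.17. The list's mean was 0.19 and its median -0.045, and it did not pass (adjusted p = 0.893 by camera). Of 40 genes of eicosanoid and lysophospholipid metabolism and receptors, 14 lay above 0 and none passed adjusted over the list alone. The prostaglandin synthase genes Ptges2 and Hpgds differed by 0.45 ± 0.21 and -1.39 ± 0.84, and the lysophosphatidic acid receptor gene Lpar2 by 0.28 ± 0.14. That list did not pass (adjusted p = 0.280 by camera), and neither did the sebaceous gland list, where 18 members lay above 0 and 16 below (adjusted p = 0.943 by camera). In it Plin2 differed by 0.35 ± 0.18 and Scd3 by -0.43 ± 0.20.

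**Figure D3:**
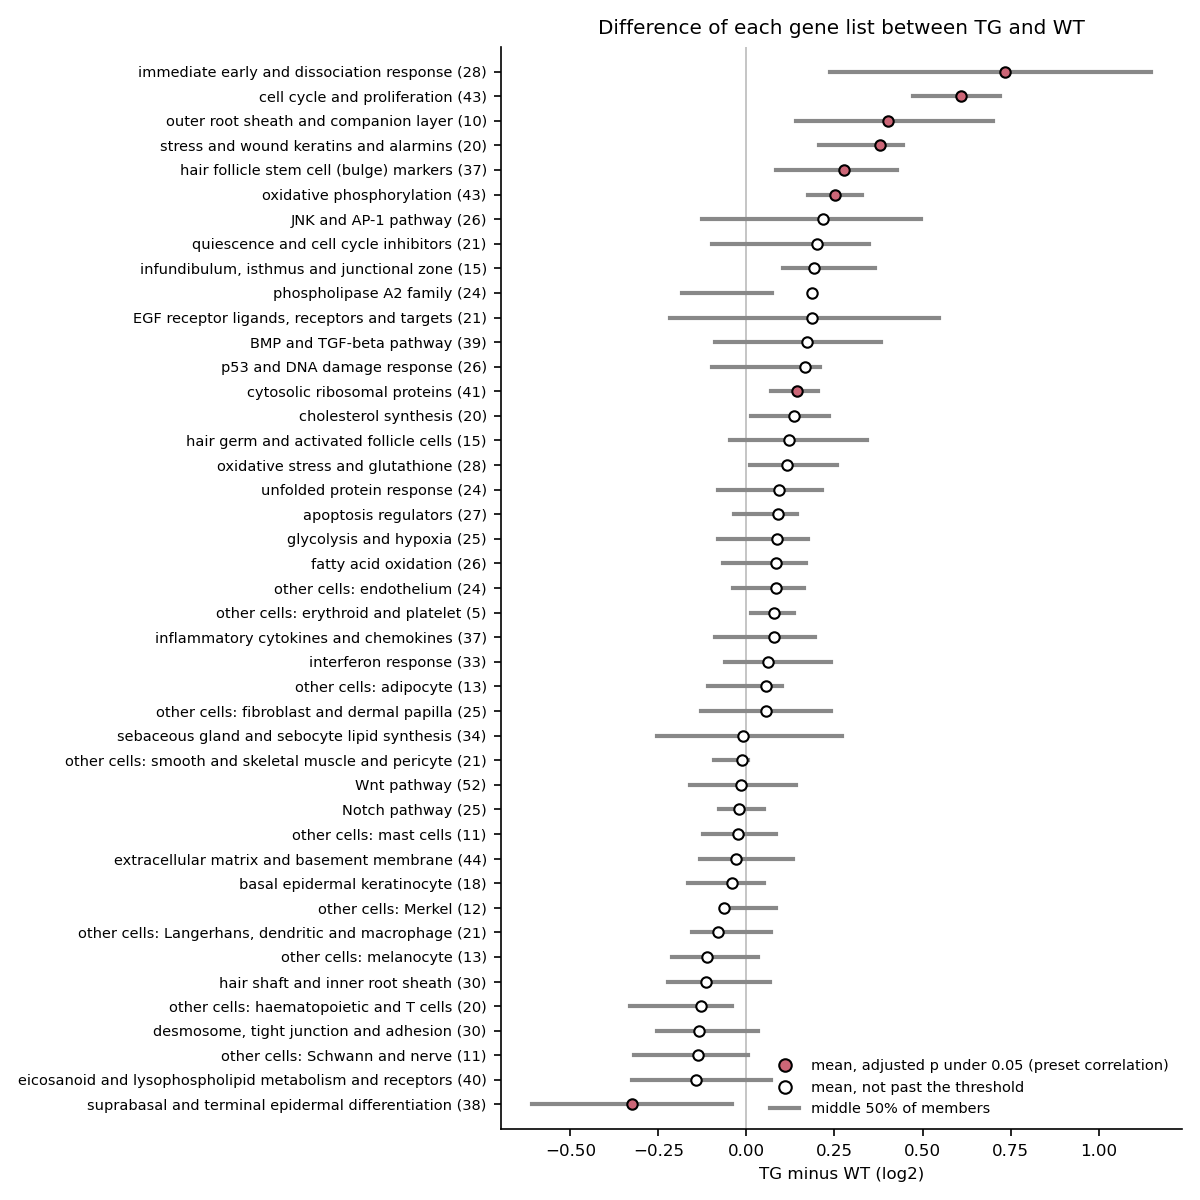
Mean TG minus WT difference (log2, horizontal axis) of each of the 43 gene lists, with the number of measured members in brackets; grey bars span the middle 50% of members and filled points mark adjusted p under 0.05 by camera with the preset correlation. The immediate early list (0.73) and the cell cycle list (0.61) lie farthest to the right and the suprabasal list (-0.32) farthest to the left. None passed with an estimated correlation.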

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

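The fits without both arrays of a number and with a covariate were chosen after seeing the data. Of 2207 values of 101 named genes under the alternatives, 2185 kept direction and side of the threshold, 18 changed sign and 0 were newly past it. All of these genes but Pla2g2a were not past the threshold to begin with. Many were named because their genotypes did not overlap, so leaving out arrays could not change their sign. Of 348 values of 14 lists, 270 kept direction and side, 8 changed sign, 37 were no longer past the threshold and 33 newly past it. Pla2g2a kept a difference between 6.16 and 6.70 when arrays were left out and 6.38 with no moderation of the variances, where its call was lost (adjusted p = 0.292). Over all alternatives its adjusted p lay between 0.000242 and 0.292. Leaving out arrays gave 0 to 1 genes higher and 0 to 1 genes of the fixed lists, 5 to 16 lists higher and 0 to 5 lower, and 1 to 33 list members higher and 0 to 2 lower adjusted over the list alone. No moderation gave 0 genes, 0 genes of the fixed lists, 1 list member higher and 0 lists lower. An unadjusted p under 0.05 gave 158 genes higher and 57 lower at 1.5-fold, and 40 and 7 at 2-fold. An estimated correlation and fry each gave 0 lists higher and 0 lower. Array weights gave 11 lists higher and 5 lower, with 76 members higher and 9 lower. All features gave 11 lists higher and 0 lower, and genes above the median level 3 lower. The suprabasal covariate gave 2 genes higher, Pla2g2a and Mir1938 (1.73 ± 0.14 SE), the latter chosen after its values were seen. It gave 16 lists higher, 50 members higher and 1 lower, and turned Cd34 to -0.25, Lgr5 to -0.25, Itga6 to 0.00072 and the T-cell list to 0.15. The T-cell covariate gave 15 lists higher and 4 lower, with 40 members higher and 9 lower. With the suprabasal covariate the infundibulum (adjusted p = 0.00242), JNK (0.00444), quiescence (0.0273), EGF receptor (0.0320), p53 (0.00447), oxidative stress (0.00242), cholesterol (0.00242), fatty acid oxidation (0.0148), glycolysis (0.0152) and unfolded protein lists (0.00712) passed as higher and the matrix list as lower (0.00221), and the bulge call was lost (0.778). With the T-cell covariate the infundibulum (0.0104), JNK (0.0104), quiescence (0.0365), BMP (0.0386), p53 (0.0359), oxidative stress (0.0104), cholesterol (0.0386) and unfolded protein lists (0.0359) passed as higher and the eicosanoid (0.0365), desmosome (0.0499) and Schwann lists (0.0448) as lower. Genes above the median level called the desmosome (0.0213) and Schwann lists (0.0236) lower. With an estimated correlation 0 lists passed under either covariate (lowest adjusted p = 0.329 and 0.606, with 3 and 2 lists at an unadjusted p under 0.05) or with genes above the median level (lowest 0.749, 1 list), a test chosen after seeing the data. The replicate block gave 3 lists lower, 32 members higher and 4 lower. Besides the calls given with paired values, and 1 member higher in the BMP list and 1 lower in the macrophage list adjusted over the list alone, it changed no other call.

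With arrays left out, Cd34 ran from -0.45 to 1.37, Lgr5 from -0.46 to 1.48, Krt15 from -0.053 to 0.13, Lhx2 from -0.093 to 0.63, Mapk8 from -0.12 to 0.30 and Itga6 from -0.18 to 0.062. The bulge list ran from -0.084 to 0.78, the suprabasal list from -0.85 to 0.18, the T-cell list from -0.64 to 0.30 and the desmosome list from -0.32 to 0.026. The cause was not tested. Without both arrays numbered 2 or 3 the call of Pla2g2a was lost (adjusted p = 0.140 and 0.173), with 2 arrays left per genotype. Signal over background was not used here, so what it limits is unknown.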

Other observations

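Several lists outside those described above held genes with differences of more than 1.5-fold, none past the threshold over all genes. Hk2, with 0.78 ± 0.15 (SE), was the 1 glycolysis and hypoxia gene higher adjusted over the list alone, and Hif1a, encoding the hypoxia-inducible factor subunit, was at 0.48 ± 0.17. Ndrg1 and Slc16a3 of the same list went the other way, at -0.57 ± 0.27 and -0.30 ± 0.16. The list did not pass (15 of 25 above 0, adjusted p = 0.493 by camera). In the list of EGF receptor ligands and targets, the ligand genes Hbegf, Nrg1 and Epgn were at 1.82 ± 0.57, 0.80 ± 0.28 and 0.70 ± 0.22, and Dusp6, a feedback phosphatase gene of the pathway, was at 0.76 ± 0.25. None passed adjusted over that list alone, 1 member was higher when paired by number, and the list did not pass (10 of 21 above 0, adjusted p = 0.110 by camera). Among cytokines the monocyte attractant gene Ccl2 was at 1.30 ± 0.41, Tslp at 0.35 ± 0.14 and Csf1 at -0.59 ± 0.23 (20 of 37 above 0, adjusted p = 0.307 by camera). Interferon response genes went both ways, with Rtp4 at 0.59 ± 0.13 and Usp18 at -0.88 ± 0.35 (19 of 33 above 0, adjusted p = 0.213 by camera). In the matrix list, Lama1 was at -1.33 ± 0.55 and Mmp9 at -0.59 ± 0.22 beside Fn1 at -0.77 ± 0.18, and paired by number 2 members were lower adjusted over the list alone (18 of 44 above 0, adjusted p = 0.267 by camera).

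Among hair germ genes, Sostdc1, encoding a secreted BMP and Wnt antagonist, was at 0.57 ± 0.16 (SE) and the Wnt ligand gene Wnt10b at -0.53 ± 0.16 (10 of 15 above 0, adjusted p = 0.310 by camera). Dlx3, a transcription factor gene of the hair shaft, was at -0.50 ± 0.18 (10 of 30 above 0, adjusted p = 0.266 by camera). The anti-apoptotic gene Bcl2a1a was at 0.94 ± 0.22 (17 of 27 apoptosis regulators above 0, adjusted p = 0.125 by camera). In fatty acid oxidation, Acadl was at 0.60 ± 0.14 and Pdk4 at 1.27 ± 0.66 (15 of 26 above 0, adjusted p = 0.231 by camera). The glutathione genes Gclm and Gstm2 were at 0.68 ± 0.24 and 0.49 ± 0.17 (21 of 28 above 0, adjusted p = 0.0595 by camera). Insig1, a sterol sensor gene, was at 0.84 ± 0.29 (15 of 20 cholesterol synthesis genes above 0, adjusted p = 0.187 by camera), and the endoplasmic reticulum genes Calr and Creld2 were at 0.40 ± 0.13 and 0.37 ± 0.13 (16 of 24 above 0, adjusted p = 0.0639 by camera). In 7 lists the mean, the median and the test differed in sign, namely the phospholipase A2, EGF receptor, Wnt, Notch, sebaceous, adipocyte and Merkel lists, and none of these passed by camera in the unpaired fit of the 22180 genes without weights or covariates. Paired by number, 1 hair shaft gene was lower adjusted over the list alone.

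Several of these lists passed by camera with other processing of the 6 arrays or once 1 array was left out. With all features, apoptosis (adjusted p = 0.00235), EGF receptor (0.0364), unfolded protein response (0.0447) and oxidative stress genes (0.0460) passed as higher, and with array weights oxidative stress (0.0210) and fatty acid oxidation genes (0.0231). The unfolded protein response list also passed with no moderation (0.0138). Without TG array 3 the lists of oxidative stress (0.000787), EGF receptor (0.00201), fatty acid oxidation (3.3e-05), glycolysis and hypoxia (0.00402), unfolded protein response (0.00621), p53 response (0.00362) and apoptosis genes (0.0341) passed as higher and the matrix list as lower (0.00362). Without WT array 1, oxidative stress (0.0156), unfolded protein response (0.00908) and cholesterol synthesis genes (0.000547) passed as higher and matrix genes as lower (0.0294). Without WT array 2, the same 3 lists passed as higher (0.0382, 0.0374 and 0.00585), as did the EGF receptor (0.0374) and p53 lists (0.0121), while the matrix (0.0308) and hair shaft lists (0.0492) passed as lower. The cholesterol synthesis list passed as lower without WT array 3 (0.000144), so its direction changed with single arrays. With an estimated correlation none of these calls held (adjusted p from 0.514 to 0.838), the one with no moderation aside, for which that test was not run.

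Among the tests below, those of cell shares on the arrays numbered 3, of heat-shock genes and of a single array were chosen only after the result was seen. The suprabasal covariate used below was added after seeing the data as well. With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real split gave 1 gene and 8 lists, and 2 and 6 of the 10 splits gave as many or more. The highest other counts were 1051 genes, for WT arrays 1 and 2 with TG array 2 against the rest, and 17 lists. A split that calls 1051 genes points to a structure of the samples other than genotype. With an estimated correlation this split too gave 0 lists, so a list lost by that test may still differ. Among the 4 splits that part all 3 pairs, the paired fit gave 1 gene and 12 lists for the real split, and 0 genes and between 10 and 12 lists for the other 3.

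The arrays numbered 3 differed from the others in both genotypes, with Cd34 at 9.41-fold and 3.51-fold the level of the other WT and TG arrays. Quantile normalization kept at least 101.1% of the contrast between the bulge and suprabasal lists in both genotypes. The quartiles of the deposited values were nearly equal beforehand, so it changed little. Unequal distributions of these values thus did not account for the contrast, but scaling before deposit and other technical causes were not tested. A candidate explanation is that the other sorts held more suprabasal keratinocytes and T cells, since the haematopoietic and T-cell list mean differed by at least -1.19 on array 3 in both genotypes while the suprabasal list was lower and the bulge list higher. The most abundant gene of each list, chosen after its values were seen, was lowest on array 3 in both genotypes, with Krt10 at 14.05, 14.12 and 13.26 in WT and 13.69, 14.10 and 13.01 in TG and Cd7 at 10.99, 10.91 and 8.93 in WT and 9.53, 11.25 and 8.71 in TG on arrays 1 to 3, although a gate on CD34 and α6-integrin would be meant to remove such cells. Of the lists' genes, 1 of the T-cell list and 5 of the suprabasal list stand in another list too, and whether the mice themselves differed was not tested. Other lists also differed on array 3 in WT and TG, among them the sebaceous (-0.85 and -0.62), endothelium (0.46 and 0.49) and matrix lists (0.52 and 0.42). The candidate explanation as stated does not name these.

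The mean of the immediate early list was higher in TG on each pair of arrays, although its call was lost with an estimated correlation (adjusted p = 0.646) and by fry (adjusted p = 0.865). The same order of pairs held for lists that did not pass by camera, such as JNK and AP-1 (adjusted p = 0.158) and glycolysis and hypoxia (adjusted p = 0.493). Adjusted over the immediate early list alone but not over all genes, 5 of its 28 members passed as higher. With the suprabasal list as a covariate the difference of the list mean was 0.87 ± 0.16 (SE), against 0.73 ± 0.36 without it. Both list means were lower on the arrays numbered 3 in WT and TG, by -0.48 and -0.94 for immediate early and -1.59 and -1.51 for suprabasal genes. They thus varied together between arrays. Even so, the fit with the covariate gave no smaller genotype difference. With 6 arrays and a list mean as the only stand-in for cell share, this fit cannot exclude a different share of suprabasal keratinocytes. General stress during dissociation stays open. In the unpaired fit the 6 heat-shock members differed by 0.19 ± 0.21 (SE) and the other 22 members by 0.88 ± 0.41, too wide to decide. No paired fit was made for these parts of the list. Handling that differed between genotypes and an effect of the transgene cannot be told apart here, because the labels do not give the order or duration of the sorts.

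The mean of the cell cycle list was higher in TG on each pair of arrays too, although its call was lost with an estimated correlation (adjusted p = 0.646) and by fry (adjusted p = 0.865), and 0 of 43 members passed adjusted over the list alone, with 17 at an unadjusted p under 0.05 in limma. Both tested explanations stay open. With the suprabasal list as a covariate the difference of the list mean was 0.57 ± 0.31 (SE), close to the 0.61 ± 0.28 without it but within 2 SE of 0. Without TG array 3 it was 0.41, which is 67.6% of the value over all arrays. More dividing cells in TG follicles may also account for it, which no value here tests.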
